A study of Mus musculus with 12 samples.

How the data were processed

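Livers of 12 mice were profiled by RNA-seq: 3 WT littermates and 3 Lix1l knockouts on LFD, and 3 of each on HFD, fed for 12 weeks from 6 weeks of age. Per the labels' protocols, livers were snap-frozen and poly(A) RNA libraries were made with a TruSeq kit. Per the submitters' processing notes, reads were aligned with HISAT2 and transcripts assembled and quantified with StringTie against build mm10, and the versions are not given in the sources used here. The authors deposited 1 table of TPM, with values that sum to the same total in each of the 12 libraries and 56107 genes, of which 55487 have an Ensembl identifier and 620 are loci assembled by StringTie. A symbol is given for 55141 of them. TPM divides by transcript length and by the library's total, so the table holds no counts, the depth of each library is unknown, and no interval from counting was computed. Columns of group means in the same table were compared with means recomputed from the libraries and differed by at most 3.33e-05 TPM, which also showed which library columns hold the knockouts, whose names use another abbreviation. Positions and gene types are from GENCODE M21 on GRCm38.

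Groups, comparisons, tests, gene lists and alternatives were chosen before the data were examined, except where a choice is described as made after values were seen. Genes with at least 1 TPM in at least 3 of the 12 libraries were tested (11980 genes). The values log2(TPM + 1) were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, 8 residual degrees of freedom, empirical Bayes moderation with a trend, 2-sided tests and Benjamini-Hochberg adjustment over the genes tested in each comparison, and genes with adjusted p below 0.05 were called. The 6 comparisons were livers labelled knockout against WT on each diet, HFD against LFD in each genotype, the interaction of genotype and diet, and the difference between genotypes averaged over the diets. Lix1l and Cd36 were also tested by an exact 2-sided permutation of the TPM values, which with 3 against 3 cannot give p below 0.1. Correlations across genes were set beside the mean of 100 simulations of unchanged groups that share libraries in the same way, with noise drawn independently for each gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

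Of 34 gene lists, 25 with at least 5 tested members were tested in each comparison with camera in limma, with a preset correlation between genes of 0.01 and, beside it, with the correlation estimated from the data, each adjusted over the 25 lists. The lists were de novo lipogenesis and desaturation, fatty acid uptake and lipid droplet, fatty acid oxidation and PPARA targets, cholesterol synthesis and SREBP2 targets, bile acid synthesis and transport, glucose metabolism, extracellular matrix and stellate cell, cytokines and chemokines, acute phase, Kupffer cell and macrophage markers, recruited and lipid-associated macrophage markers, T and NK cell markers, B and plasma cell markers, neutrophil markers, endothelial markers, cholangiocyte markers, hepatocyte secreted proteins and identity, cell cycle, hepatocellular carcinoma and fetal liver markers, interferon response, unfolded protein and integrated stress response, oxidative stress and NRF2 targets, drug-metabolizing cytochromes, circadian clock, male-biased liver genes, female-biased liver genes, sex chromosome genes, pancreas markers, adipose markers, skeletal muscle markers, erythroid markers, mitochondrially encoded genes, genes near Lix1l on its chromosome and the pair of Lix1l and Cd36. The count of changed members is given over all genes tested and adjusted over the list alone. With the preset correlation, 7, 10, 9, 3, 5 and 11 lists passed in the 6 comparisons in the order given above, and with the estimated correlation 0 in each, with a lowest adjusted p of 0.254. The genes named were Lix1l and Cd36, the 8 largest rises and 8 largest falls of each comparison among called genes with a mean of at least 1 TPM and, except for the interaction, no overlap between the groups' values, leaving out unnamed, predicted and clone-based gene symbols, and up to 4 members of each list with the lowest p, passed or not. Of the list members that this rule allows, the ones printed were picked after their values were seen, and some genes that the rule allows, among the largest changes too, are not reported here. Genes outside the rule are described as chosen after their values were seen. A gene of which at least 0.5 of the 31-base words of its transcripts occur in another gene is described as uncertain, since reads from copies cannot be assigned.

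Alternatives were other pseudocounts, no filter and a stricter filter, median-ratio scaling, quantile normalization, fits of only the 2 groups compared, array weights, a robust prior without a trend, the animal numbers as a block and leaving out each library in turn. A count-based model was planned if the table held counts, and was not run. After the data were seen, 5 alternatives were added: leaving out the 37 mitochondrial genes and 7 nuclear copies with rescaling, a correction for GC content and transcript length by splines, protein-coding genes only, leaving out genes with copies, and leaving out KO LFD libraries 2 and 4. The procedure was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. In the 6 comparisons it recovered 49, 45, 37, 35, 6 and 81 of the 100 changed by 1, and 90, 93, 96, 93, 76 and 98 of those changed by 2, and called 6, 2, 4, 3, 3 and 13 unchanged genes. No sample was left out of the main comparisons.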

Results

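RNA-seq profiles of 12 mouse livers were compared in 4 groups of 3 animals: wild-type littermates and Lix1l knockouts, each fed a low-fat diet (LFD) or a high-fat diet (HFD) for 12 weeks from 6 weeks of age. Feeding a diet rich in fat to mice is a common way to bring on fatty liver disease, and its inflamed form is non-alcoholic steatohepatitis (NASH). The series asks how LIX1L affects NASH. Each liver gave 1 library of polyadenylated RNA, and each gene's level was given in TPM, which is scaled to transcript length. TPM sums to the same total in every library and keeps no read depth, so the depth of each library is unknown. In all, 11980 genes reached 1 TPM in at least 3 libraries. Between 10265 and 11353 genes reached 1 TPM in a library. Spearman correlations across genes ran from 0.907 to 0.967 between libraries of the same group and from 0.807 to 0.949 between libraries of different groups. Every library held Y-linked Ddx3y (7.45 to 14.2 TPM) and at most 0.120 TPM of Xist, the transcript of the inactive X chromosome. Values below are mean ± SD in TPM with n = 3 per group. The log2 changes are on the log2(TPM + 1) scale with their SE after the ± sign, which understates the change of genes of low level. Adjusted p is from limma.

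The level of Lix1l itself did not separate the genotypes. Lix1l (ENSMUSG00000049288, a protein-coding gene on the + strand of chromosome 3, 96601149 to 96626171, GRCm38) was at 0.793 ± 0.258 TPM in WT LFD, 0.420 ± 0.313 TPM in KO LFD, 1.27 ± 0.422 TPM in WT HFD and 1.15 ± 0.907 TPM in KO HFD livers. The 3 KO HFD libraries, numbers 1, 5 and 6, held 1.92, 0.150 and 1.38 TPM, which spans the range of the WT HFD libraries (0.900 to 1.73 TPM). The difference was within the spread between animals on HFD (log2 change -0.17 ± 0.31, adjusted p = 0.695, exact permutation p = 0.9) and on LFD (log2 change -0.35 ± 0.31, adjusted p = 0.716, exact permutation p = 0.3). The exact tests were 2-sided, and 3 against 3 animals cannot give p below 0.1. Lix1l changed sign on HFD without KO HFD library 5 (log2 change 0.23, adjusted p = 0.489). It passed the test when libraries were weighted by their quality (log2 change -0.73, adjusted p = 0.0138), the lowest adjusted p over all alternatives, which ran up to 0.996. Which part of Lix1l was deleted is not given in the sources used here, and a gene total can hold transcript from outside the deleted part. Because Lix1l does not check the genotype of the KO HFD libraries, animals are described throughout as labelled knockout, and every direction between genotypes rests on those labels.

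Cd36, which encodes a fatty acid translocase of the plasma membrane and is named in the title of the series, was lower in HFD livers labelled knockout than in WT HFD livers. Cd36 (ENSMUSG00000002944, protein-coding, - strand of chromosome 5, 17781690 to 17888801, GRCm38) was at 50.2 ± 9.43 TPM in WT HFD and 8.42 ± 3.09 TPM in KO HFD livers, a ratio of means of 5.96 (log2 change -2.47 ± 0.36, adjusted p = 0.00135). All 3 KO HFD values (6.59 to 12.0 TPM) lay below the WT HFD values (39.7 to 58.0 TPM), with the smallest exact p that the design allows, 0.1. On LFD, Cd36 was at 10.5 ± 6.84 TPM in livers labelled knockout and 13.7 ± 2.81 TPM in WT livers, a difference within the spread between animals (log2 change -0.49 ± 0.36, adjusted p = 0.642, exact permutation p = 0.5). In WT livers the mean was 3.65 times as high on HFD as on LFD, which did not pass the test across all genes (log2 change 1.80 ± 0.36, adjusted p = 0.0726, exact permutation p = 0.1). It passed without KO LFD library 2 (adjusted p = 0.0400) or 5 (adjusted p = 0.0158), with adjusted p of 0.00287 to 0.749 over all alternatives. In livers labelled knockout the difference between the diets was within the spread between animals (log2 change -0.19 ± 0.36, adjusted p = 0.727, exact permutation p = 0.8). Without KO LFD library 5 the sign of that change turned (log2 change 0.27).

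**Figure D1:**
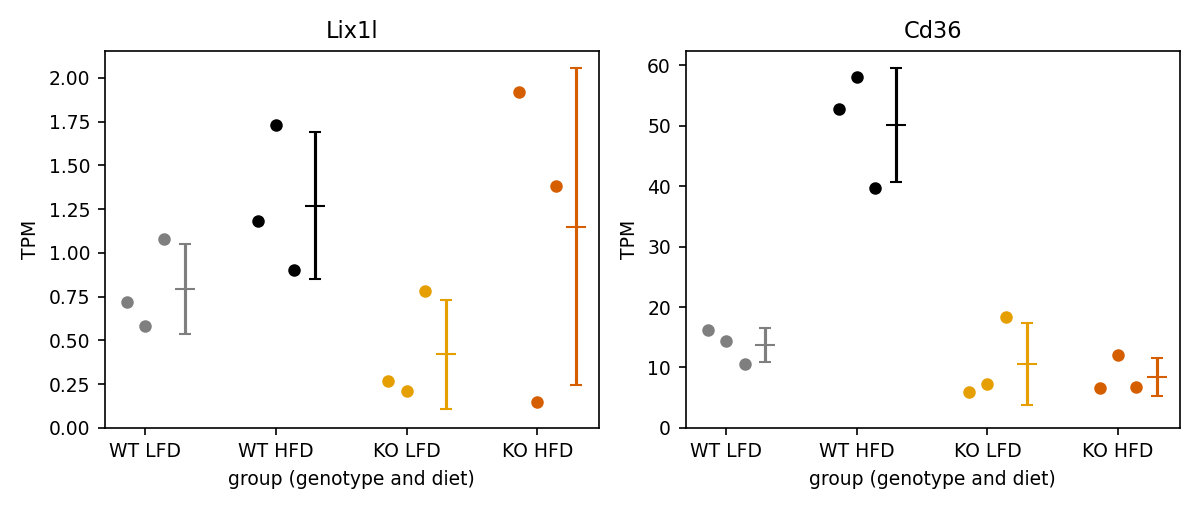
Lix1l and Cd36 in TPM (y axes) in each of the 12 livers (points) by group (x axes), with the group mean and SD (bars, n = 3). The Lix1l values of the KO HFD group run from 0.150 to 1.92 TPM, and the 3 WT HFD livers hold the highest Cd36 values, from 39.7 to 58.0 TPM.

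On HFD, livers labelled knockout had lower levels of many genes that hepatocytes use to burn fatty acids and make bile acids, and higher levels of markers of endothelial cells, macrophages and matrix-producing cells, than WT livers. Each list call on HFD was lost with estimated correlation (lowest adjusted p = 0.508). Beside Cd36, Slc27a2 (443 ± 80.6 against 1199 ± 17.1 TPM), Cpt1a (36.6 ± 8.64 against 118 ± 18.5 TPM) and Cyp8b1 (72.4 ± 23.9 against 283 ± 38.1 TPM) were lower. Among endothelial markers, Egfl7 (25.8 ± 2.28 against 8.67 ± 1.51 TPM) and Pecam1 (3.53 ± 0.773 against 0.997 ± 0.693 TPM) were higher. In all, 1347 genes were higher and 3088 lower, 4435 in total or 37.0% of the 11980 tested. A change of more than 1 on the log2 scale was seen for 2090 of these calls and of more than 2 for 239 of them.

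The 69.6% of these calls that were lower became 55.1% of 4774 with median-ratio scaling, 55.8% of 4785 with quantile normalization, 57.3% of 4784 without mitochondrial genes and their nuclear copies and 53.6% of 4594 with a correction for GC content and length. The median log2 change over all tested genes was -0.25, and these 4 scalings raised it by 0.19, 0.18, 0.15 and 0.20. The count of 4435 dropped to 2327 without WT HFD library 1 and to 2617 without WT HFD library 6. The KO HFD libraries stood apart from the rest on the first principal component (38.7% of the variance, scores of 42.9 to 84.9 against at most 0.390 elsewhere). Mitochondrially encoded genes took 15.3% ± 6.30 of TPM in the KO HFD group, 9.44% ± 1.45 in WT HFD, 8.10% ± 0.627 in KO LFD and 10.8% ± 1.29 in WT LFD. KO HFD library 1 held the highest share (22.6%), and without it 3286 genes passed, 58.1% of them lower.

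**Figure D2:**
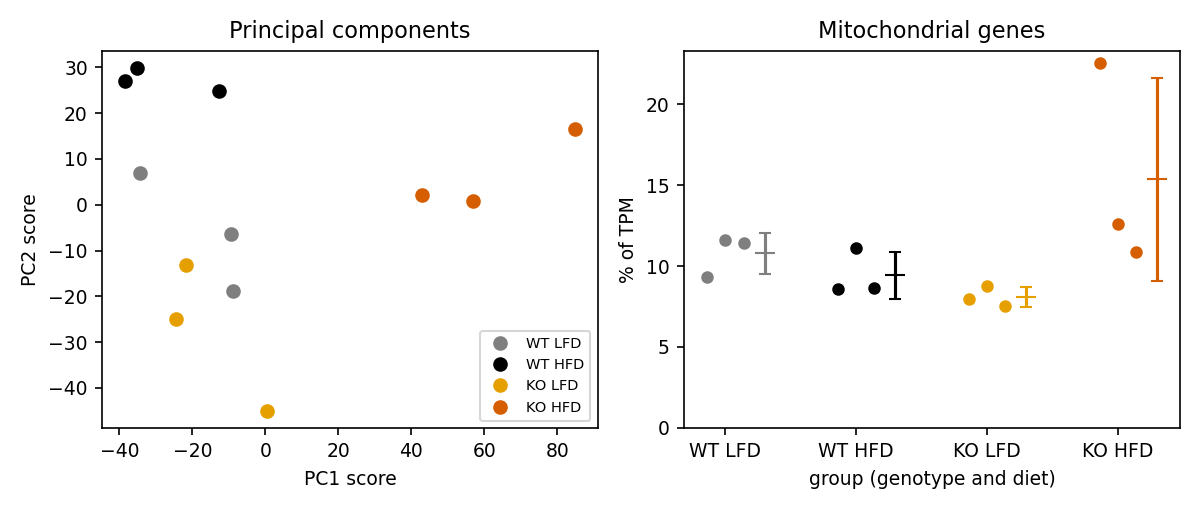
Left, scores of the 12 livers (points) on the first and second principal components (x and y axes, arbitrary units) of the tested genes, coloured by group. Right, mitochondrially encoded genes as % of TPM (y axis) by group (x axis), with group mean and SD (bars, n = 3): KO HFD livers lie at 10.9 to 22.6%.

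Many genes of fatty acid oxidation and of fatty acid uptake were lower in the HFD livers labelled knockout, and of these lists only that of oxidation passed, close to the threshold. In the list of fatty acid oxidation and PPARA targets, 12 of 27 fell and none rose (12 adjusted over the list alone, median log2 change -0.79, camera adjusted p = 0.0496, and 0.821 with estimated correlation). They included Hadha, a subunit of the mitochondrial trifunctional protein, at 37.1 ± 11.5 TPM against 125 ± 30.7 TPM (log2 change -1.74 ± 0.32, adjusted p = 0.00298), and Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria. The call on this list was lost without WT LFD library 4 (adjusted p = 0.0529), WT HFD library 2 (0.0999), KO HFD library 5 (0.1) or KO HFD library 6 (0.0779). Of the 24 genes of fatty acid uptake and lipid droplets, 11 fell and 2 rose (11 and 2 adjusted over the list alone, median log2 change -0.94, camera adjusted p = 0.0842). The lipid droplet coat gene Plin3 (log2 change -1.63 ± 0.25, adjusted p = 0.00164) and the bile acid and fatty acid CoA ligase Slc27a5 (log2 change -1.27 ± 0.23, adjusted p = 0.00287) fell with Cd36. De novo lipogenesis went both ways, with 2 of 16 genes higher and 5 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.834). Mlxipl, which encodes the carbohydrate-responsive transcription factor ChREBP, rose to 55.1 ± 20.2 TPM against 17.4 ± 4.23 TPM (log2 change 1.57 ± 0.32, adjusted p = 0.00429). Me1, Elovl5 and Dgat2, which acts in triglyceride synthesis, fell (adjusted p = 0.0125 to 0.0142).

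Bile acid genes fell as a list (12 of 19, 13 adjusted over the list alone, median log2 change -0.87, camera adjusted p = 0.00856, and 0.722 with estimated correlation). Cyp8b1, the sterol hydroxylase that sets the ratio of cholic acid, was at 72.4 ± 23.9 TPM against 283 ± 38.1 TPM (log2 change -1.99 ± 0.32, adjusted p = 0.00194). The sterol exporter Abcg8 was at 7.54 ± 1.43 TPM against 26.7 ± 3.52 TPM (log2 change -1.71 ± 0.26, adjusted p = 0.00160). Targets of the antioxidant factor NRF2 fell too (10 of 16, 10 adjusted over the list alone, median log2 change -0.99, camera adjusted p = 0.0496, and 0.722 with estimated correlation). Catalase, Cat, was at 709 ± 96.4 TPM against 1405 ± 63.9 TPM (log2 change -0.99 ± 0.22, adjusted p = 0.00611). The NRF2 call was lost without WT LFD library 4 (adjusted p = 0.0538), WT HFD library 2 (0.135), KO HFD library 5 (0.0552) or KO HFD library 6 (0.0779). Among glucose genes, 7 of 15 fell (adjusted over the list alone, 7 fell and 1 rose, camera adjusted p = 0.109). Fbp1, an enzyme of gluconeogenesis, was at 185 ± 105 TPM against 680.1 ± 175 TPM (log2 change -2.06 ± 0.43, adjusted p = 0.00518). Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes, fell as well. Of cholesterol synthesis genes, 4 of 25 fell (1 adjusted over the list alone, camera adjusted p = 0.524). Genes of hepatocyte identity and secreted proteins fell in 12 of 20 cases and rose in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.0842). Apob, the structural protein of very-low-density lipoprotein, was at 661 ± 89.4 TPM against 1156 ± 52.1 TPM (log2 change -0.81 ± 0.17, adjusted p = 0.00527), and the hepatocyte transcription factor Cebpa (77.8 ± 18.1 against 156 ± 7.71 TPM) fell as well. Acute phase genes fell in 6 of 20 cases (5 adjusted over the list alone, camera adjusted p = 0.0842), among them C-reactive protein, Crp, and the fibrinogen chains Fga and Fgb (adjusted p = 0.00355 to 0.00851).

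Endothelial, Kupffer cell and matrix genes shifted upward as lists on HFD. Of 11 endothelial markers, 10 rose (10 adjusted over the list alone, median log2 change 0.96, camera adjusted p = 1.41e-07, and 0.508 with estimated correlation). Fcgr2b, an inhibitory Fc receptor of sinusoidal endothelium, was at 19.8 ± 1.47 TPM against 4.55 ± 1.81 TPM (log2 change 1.95 ± 0.25, adjusted p = 7.61e-04). Tek, the angiopoietin receptor, was at 1.31 ± 0.0643 TPM against 0.320 ± 0.173 TPM (log2 change 0.82 ± 0.16, adjusted p = 0.00406). Of 14 Kupffer cell and macrophage markers, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median log2 change 1.41, 0.87 to 1.94 without 1 library, camera adjusted p = 4.89e-04, and 0.722 with estimated correlation). The Kupffer cell lectin Clec4f was at 76.5 ± 55.5 TPM against 12.7 ± 7.38 TPM (log2 change 2.29 ± 0.60, adjusted p = 0.0135). Timd4, a receptor of resident macrophages, was at 4.39 ± 2.25 TPM against 0.590 ± 0.416 TPM (log2 change 1.72 ± 0.36, adjusted p = 0.00512). Extracellular matrix and stellate cell genes rose in 7 of 22 cases (7 adjusted over the list alone, median log2 change 0.44, camera adjusted p = 1.10e-04, and 0.722 with estimated correlation), with collagen gene Col6a1 (1.57 ± 0.321 against 0.503 ± 0.167 TPM) and Vim (11.1 ± 3.18 against 3.95 ± 0.693 TPM) as examples. The mitochondrially encoded genes rose as a list (7 of 13, 9 adjusted over the list alone, median log2 change 0.89, camera adjusted p = 8.59e-05, and 0.722 with estimated correlation). In that list mt-Nd1 was at 13856 ± 5658 TPM against 4680.3 ± 1508 TPM (log2 change 1.54 ± 0.32, adjusted p = 0.00488). Mitochondrial share and the markers of these cells moved together with the KO HFD group, as did the nuclear RNAs Malat1 (79.0 ± 43.6 against 6.79 ± 2.31 TPM) and Neat1 (122 ± 68.9 against 14.6 ± 7.75 TPM), which were chosen after their values were seen.

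Other lists did not shift as a whole on HFD. Interferon response genes went both ways, and 3 rose and 1 fell of 20 (3 and 1 adjusted over the list alone). The signal transducer Stat2 was at 25.9 ± 7.81 TPM against 8.42 ± 0.433 TPM (log2 change 1.47 ± 0.24, adjusted p = 0.00200) and the oligoadenylate synthetase Oas2 rose (adjusted p = 0.00268), whereas the guanylate-binding protein gene Gbp2 fell (adjusted p = 0.0117). The median of that list was -0.10, its mean 0.03 and its test upward (camera adjusted p = 0.314), and the median turned positive with every scaling tried, up to 0.14. In the hepatocellular carcinoma and fetal liver list, 1 rose and 3 fell of 7 (1 and 3 adjusted over the list alone, camera adjusted p = 0.361). Cyclin D1, Ccnd1, was at 1.69 ± 0.430 TPM against 8.79 ± 2.73 TPM (log2 change -1.84 ± 0.30, adjusted p = 0.00195). In the cell cycle list 0 rose and 2 fell of 9 (0 and 2 adjusted over the list alone, camera adjusted p = 0.437, median -0.36 and 0.03 with the GC and length correction), with the DNA clamp Pcna (9.17 ± 3.47 against 19.4 ± 1.51 TPM) lower. Of cytokines and chemokines, 2 rose and 1 fell of 14 (1 and 0 adjusted over the list alone, camera adjusted p = 0.0646), with Il1a (1.83 ± 0.518 against 0.537 ± 0.162 TPM) higher. The counts were 2 rose and 1 fell of 17 for the unfolded protein and integrated stress response (camera adjusted p = 0.0842), 0 rose and 2 fell of 18 for drug-metabolizing cytochromes (0.594) and 1 rose and 1 fell of 8 for recruited macrophage markers (0.256), or 2 and 1, 0 and 2, and 0 and 0 adjusted over the list alone. In the circadian clock list, 1 rose and 2 fell of 15 (1 and 2 adjusted over the list alone, median -0.17, test upward with camera adjusted p = 0.859, and the sign of its median turned with every scaling tried), with the clock repressor Nr1d1 (12.1 ± 7.28 against 31.5 ± 5.11 TPM) and the output factor Hlf (5.71 ± 0.568 against 15.7 ± 3.73 TPM) lower.

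Of 13 genes near Lix1l on its chromosome, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.551), and the exon junction gene Rbm8a (47.4 ± 10.9 against 19.7 ± 2.50 TPM) was higher. Male-biased liver genes held 0 changed members of 13 (median -0.37, test upward with camera adjusted p = 0.979 and downward with each scaling tried), female-biased genes 1 of 5 (Abcd2, a peroxisomal transporter gene, lower, median 0.24 and mean -0.18, test upward with camera adjusted p = 0.733) and erythroid markers 0 of 5 (camera adjusted p = 0.121), with 0, 1 and 0 adjusted over the list alone. Lists with fewer than 5 tested genes were only counted. Of 3 adipose markers, Cfd and Lipe fell, and 1 of 3 B and plasma cell markers (2 adjusted over the list alone) rose. None changed among T and NK cell (2 tested), neutrophil (2), sex chromosome (4), pancreas (2) and skeletal muscle (1) genes, by limma or adjusted over the list alone, and 1 of 3 cholangiocyte markers fell.

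The largest rises and falls on HFD included genes seen at near-zero levels in one group. H2-Q1, a nonclassical major histocompatibility gene, was at 852 ± 231 TPM against 7.20 ± 4.08 TPM (log2 change 6.77 ± 0.57, adjusted p = 8.24e-05). Rny3, a small cytoplasmic Y RNA, was at 49.1 ± 17.8 TPM (adjusted p = 2.06e-07), and listed at 0 TPM in all 9 other libraries. The steroid dehydrogenase gene Hsd3b1 was at 68.2 ± 6.91 TPM against 3.21 ± 5.49 TPM (log2 change 4.94 ± 0.86, adjusted p = 0.00253) and the cytochrome gene Cyp2d34 at 528 ± 203 TPM against 0.790 ± 1.20 TPM (log2 change 8.33 ± 1.70, adjusted p = 0.00462). Among falls, Aldh4a1, an enzyme of proline breakdown, was at 1.28 ± 1.15 TPM against 88.1 ± 43.7 TPM (log2 change -5.25 ± 0.65, adjusted p = 7.09e-04). Mmd was at 1.08 ± 0.335 TPM against 68.9 ± 32.8 TPM (log2 change -4.94 ± 0.48, adjusted p = 2.21e-04). Cfd, which encodes the complement factor adipsin, was at 8.63 ± 9.13 TPM against 158 ± 98.8 TPM (log2 change -4.19 ± 0.64, adjusted p = 0.00158), and Snora20, a small nucleolar RNA at 16.5 ± 11.4 TPM in WT HFD livers, was listed at 0 TPM in all KO HFD libraries (adjusted p = 0.00587). The levels of n-R5s139, Rpl17-ps3 and Cyp2c69, which rose, and of Tmem254c, Ugt1a1, Pdf and Rps13-ps1, which fell, are uncertain, because more than 0.5 of their 31-base words occur in other genes. Mir703 rose as well, with the same uncertainty, and lost the call without WT HFD library 1 or 6 or KO HFD library 5 (adjusted p up to 0.0831), as Rps13-ps1 did without WT HFD library 1 (adjusted p = 0.0514). Of the 97 named genes that passed on HFD, 72 passed in every fit without 1 library that tested them, including the other genes named in this paragraph.

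On LFD, livers labelled knockout differed from WT livers in a high level of acute phase genes, the plasma proteins that hepatocytes release in inflammation. The list call was lost with estimated correlation (adjusted p = 0.360). The serum amyloid genes Saa1 and Saa2 were at 21153 ± 16174 TPM against 90.4 ± 48.9 TPM (log2 change 7.77 ± 0.80, adjusted p = 0.00376) and 19556 ± 20976 TPM against 40.6 ± 43.7 TPM (log2 change 8.87 ± 0.95, adjusted p = 0.00376). Fam25c was at 255 ± 100.4 TPM against 42.8 ± 6.42 TPM (log2 change 2.49 ± 0.26, adjusted p = 0.00376). The serum glycoprotein gene Orm2 was at 1640.1 ± 665 TPM against 32.7 ± 38.5 TPM (log2 change 6.20 ± 0.80, adjusted p = 0.0146). Saa3 was at 179.8 ± 13.8 TPM against 8.71 ± 7.30 TPM (log2 change 4.46 ± 0.65, adjusted p = 0.0283). Of the 31-base words of Saa1 and Saa2, shares of 0.465 and 0.465 occur in other genes.

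In all, 11 genes were higher and 8 lower on LFD, 19 in total, while 1524 had an unadjusted p under 0.05. A limma fit of these 6 libraries alone called 0 genes. The list of 20 acute phase genes rose (5 genes, or 15 higher and 1 lower adjusted over the list alone, median log2 change 2.07, camera adjusted p = 2.04e-15, and 0.360 with estimated correlation). Of the genes that fell, Gys2, the liver glycogen synthase, was at 53.5 ± 8.13 TPM against 150.5 ± 23.6 TPM (log2 change -1.47 ± 0.21, adjusted p = 0.0251). Lepr, the leptin receptor, was at 1.26 ± 1.27 TPM against 7.88 ± 2.90 TPM (log2 change -2.07 ± 0.34, adjusted p = 0.0480). The other named genes were Hpx, Ighv1-72, Slc13a3 and Asns, which rose, and Hsd17b6 and Serpinb1a, which fell (adjusted p = 0.0245 to 0.0490), and Ighv1-72 shares 0.981 of its 31-base words with other genes. Saa1, Saa2 and Fam25c passed in each of the 12 fits without 1 library. The call was lost for Orm2 and Saa3 without WT LFD library 4 or 8 (adjusted p up to 0.115 and 0.145). It was lost for Gys2 without WT LFD library 4 or 8 or WT HFD library 1 or 2 (up to 0.145). It was lost for Serpinb1a without any of the 3 WT LFD libraries (up to 0.134), and for Ighv1-72 without any of those, WT HFD library 2 or KO HFD library 6 (up to 0.145). Lepr kept it only without KO LFD library 5, Hsd17b6 and Asns only without WT LFD library 8 or KO LFD library 4. Hpx kept it only without KO LFD library 2 or 4 or KO HFD library 1 or 5, and Slc13a3 only without KO LFD library 2 or 4 or KO HFD library 5 (adjusted p up to 0.167 in the other fits). The count of 19 became 4 without WT LFD library 4, 5 without WT LFD library 8, 8, 7 and 9 without WT HFD library 1, 2 and 6, 64 without KO LFD library 4, and 12 and 8 without KO HFD library 5 and 6. With median-ratio scaling it was 52, of which 55.8% were lower against 42.1% as deposited.

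**Figure D3:**
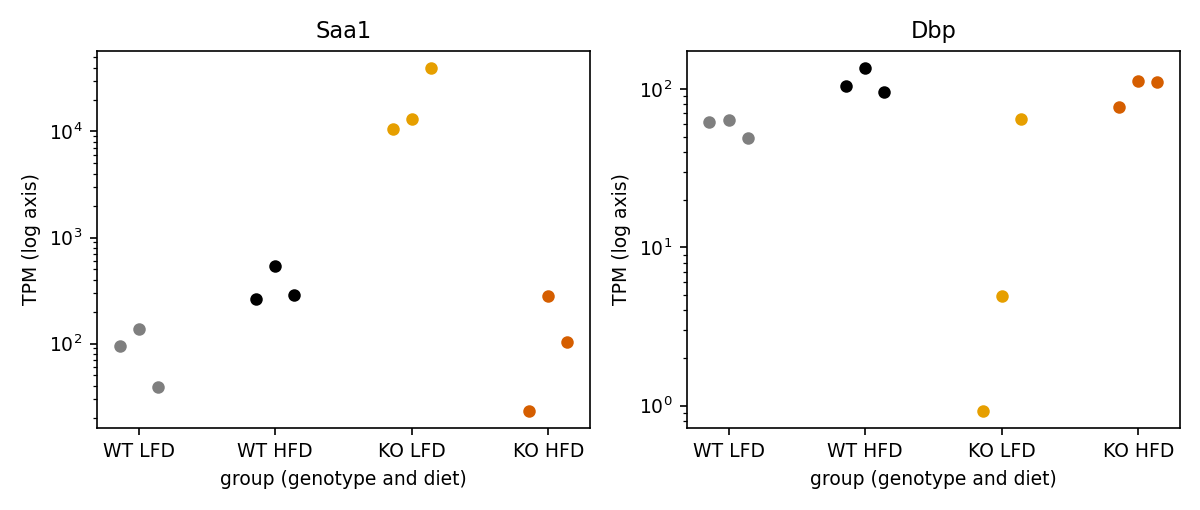
Saa1 and the clock output gene Dbp in TPM (y axes, log scale) in each of the 12 livers (points) by group (x axes). Saa1 lies between 10533 and 39768 TPM in the KO LFD livers and at most at 543 TPM elsewhere, and KO LFD libraries 2 and 4 hold the lowest Dbp values, 0.930 and 4.95 TPM.

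Other lists moved on LFD with few members passing alone. Extracellular matrix and stellate cell genes were positive in 22 of 22 cases and rose as a list (0 genes, or 11 adjusted over the list alone, median log2 change 0.70, camera adjusted p = 4.78e-11, and 0.360 with estimated correlation). Endothelial markers (10 of 11 adjusted over the list alone, 0 over all genes, camera adjusted p = 4.24e-09, and 0.360 with estimated correlation) and Kupffer cell markers (12 of 14 adjusted over the list alone, 0 over all genes, camera adjusted p = 7.83e-08, and 0.550 with estimated correlation) rose too. Examples that did not pass alone were Tgfb1 (3.59 ± 0.348 against 1.33 ± 0.378 TPM, adjusted p = 0.0940), Cdh5 (2.97 ± 0.385 against 0.933 ± 0.420 TPM, adjusted p = 0.113), Cd68 (7.87 ± 3.71 against 1.79 ± 0.864 TPM, adjusted p = 0.153) and Marco (35.0 ± 30.2 against 3.64 ± 3.50 TPM, adjusted p = 0.126). Cholesterol synthesis genes were positive in 25 of 25 cases with none past the threshold by either adjustment (median log2 change 1.09, 0.63 to 1.89 without 1 library, camera adjusted p = 1.47e-05, and 0.644 with estimated correlation), as for Fdps (307 ± 233 against 30.0 ± 6.77 TPM, adjusted p = 0.199). Fatty acid oxidation genes fell as a list (0 genes, or 9 adjusted over the list alone, median log2 change -0.73, camera adjusted p = 4.66e-13, and 0.360 with estimated correlation), with Eci1 (125 ± 24.1 against 223 ± 37.4 TPM, adjusted p = 0.132) and Vnn1 (19.7 ± 13.1 against 68.7 ± 15.7 TPM, adjusted p = 0.139). Smaller downward shifts were found for mitochondrially encoded genes (camera adjusted p = 0.00150, and 0.644 with estimated correlation), hepatocyte genes (camera adjusted p = 0.00857, and 0.615 with estimated correlation), female-biased genes (camera adjusted p = 0.0130, and 0.550 with estimated correlation) and lipid droplet genes (camera adjusted p = 0.0193, and 0.644 with estimated correlation), with 0, 1, 1 and 1 members lower adjusted over the list alone and none over all genes. The last of these lost the call without WT LFD library 4 (0.0864) or KO LFD library 2 (0.188), hepatocyte genes without KO LFD library 5 (0.143) and female-biased genes without WT LFD library 7 (0.276). Both neutrophil genes tested, S100a8 and S100a9, passed upward only when adjusted over the list alone. In the same livers the clock gene Dbp was at 0.930, 4.95 and 64.3 TPM in KO LFD libraries 2, 4 and 5 and at 58.2 ± 7.96 TPM in WT LFD livers. Without KO LFD libraries 2 and 4, a choice made after their values were seen that leaves 1 library assumed to vary like the other groups, 84 genes passed.

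In WT livers, HFD raised Cfd, Themis and Gbp10 and lowered Lepr. Cfd, the adipsin gene that fat cells express strongly, was at 158 ± 98.8 TPM against 0.430 ± 0.501 TPM (log2 change 6.58 ± 0.64, adjusted p = 0.00156). Themis, which acts in T cell selection, was at 5.48 ± 1.76 TPM against 0.157 ± 0.162 TPM (log2 change 2.46 ± 0.24, adjusted p = 0.00156). The interferon-induced guanylate-binding protein gene Gbp10 was at 9.83 ± 2.56 TPM against 0.553 ± 0.257 TPM (log2 change 2.78 ± 0.25, adjusted p = 0.00152), with 0.888 of its 31-base words in other genes. Lepr was at 0.243 ± 0.206 TPM against 7.88 ± 2.90 TPM (log2 change -2.80 ± 0.34, adjusted p = 0.00749).

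In all, 30 genes rose and 7 fell, 37 in total. Interferon response genes rose as a list (2 of 20, Ifit1 and Gbp3, or 10 adjusted over the list alone, median log2 change 0.80, camera adjusted p = 1.31e-07, and 0.687 with estimated correlation), and Ifit3 (21.2 ± 2.30 against 6.47 ± 0.577 TPM, adjusted p = 0.0807) lay short of the threshold. Adgrv1, Lgals1, Gbp6 and the lipid droplet gene Fitm1 rose, and Pdk4, a brake on glucose oxidation, Ndrg1, Psmd9 and Kctd15 fell (adjusted p = 0.00591 to 0.0483). Upward shifts were also found for cholesterol synthesis (24 of 25 positive, 0 adjusted over the list alone, camera adjusted p = 9.91e-04, and 0.687 with estimated correlation), bile acid genes (4 adjusted over the list alone, camera adjusted p = 0.00705, and 0.687 with estimated correlation), for example Abcg8 (26.7 ± 3.52 against 12.9 ± 5.08 TPM, adjusted p = 0.134), and acute phase genes (2 adjusted over the list alone, camera adjusted p = 0.0107, and 0.687 with estimated correlation). Downward shifts were found for endothelial markers (1 adjusted over the list alone, camera adjusted p = 9.73e-04, and 0.687 with estimated correlation), Kupffer cell markers (0, camera adjusted p = 0.00705, and 0.687 with estimated correlation), fatty acid oxidation genes (2, camera adjusted p = 0.0107, and 0.687 with estimated correlation), mitochondrially encoded genes (0, camera adjusted p = 0.0107, and 0.687 with estimated correlation) and matrix genes (0, camera adjusted p = 0.0432, and 0.687 with estimated correlation). Among single genes of fat uptake, Lpl (1.51 ± 0.359 against 5.97 ± 1.53 TPM, adjusted p = 0.0932) did not pass.

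Few of these calls in WT livers were kept when a WT library was left out, 1 to 12 of the 37, while 27 to 37 were kept without 1 library labelled knockout. Cfd passed in each of the 12 fits, and Themis and Gbp10 in each of the 9 fits without 1 library that tested them, since both fell below the expression filter without 1 WT HFD library. Adgrv1 and Lepr lost the call without WT HFD library 1 (adjusted p = 0.0738 and 0.0777). Lgals1, Gbp6, Fitm1, Pdk4, Ndrg1, Psmd9, Kctd15, Ifit1 and Gbp3 each lost it in 4 to 8 fits, without WT LFD libraries 4, 7 or 8, WT HFD libraries 1, 2 or 6, KO LFD library 5 or KO HFD libraries 5 or 6 (adjusted p up to 0.237). The count of 37 became 11, 15 and 11 without WT LFD library 4, 7 and 8, 1, 8 and 9 without WT HFD library 1, 2 and 6, 79 and 97 without KO LFD library 2 and 4, and 60 without KO HFD library 1. The list shift was lost for fatty acid oxidation without WT LFD library 4 (0.173, with the median turning to 0.01). It was lost for Kupffer cell markers without WT LFD library 4 (0.0506) or WT HFD library 2 (0.0661), and for acute phase genes without WT LFD library 4 (0.0968) or 8 (0.0692) or WT HFD library 2 (0.122). It was lost for mitochondrially encoded genes without WT LFD library 8 (0.102) or WT HFD library 1 (0.137) or 6 (0.0707). It was lost for matrix genes without WT LFD library 4 (0.0506) or 8 (0.437) or WT HFD library 2 (0.122) or 6 (0.0634). Of the calls, 18.9% were lower as deposited, 36.5% with median-ratio scaling, 34.9% with quantile normalization, 32.7% without mitochondrial genes and 35.9% with the GC and length correction.

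In livers labelled knockout, acute phase genes were lower, and interferon response and mitochondrially encoded genes higher, on HFD than on LFD. Each of these list calls was lost with estimated correlation (adjusted p of at least 0.976), and 9 of 20 interferon response genes passed. Saa1 and Saa2 were at 136 ± 131 TPM against 21153 ± 16174 TPM (log2 change -7.62 ± 0.80, adjusted p = 4.85e-04) and 64.3 ± 59.2 TPM against 19556 ± 20976 TPM (log2 change -8.21 ± 0.95, adjusted p = 9.65e-04). The KO LFD libraries enter this comparison and that between labels on LFD with opposite sign, so their acute phase results are not independent. Saa1 ran from 23.3 to 280 TPM in KO HFD, 39.3 to 137 TPM in WT LFD and 261 to 543 TPM in WT HFD libraries. Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, was at 12.0 ± 12.0 TPM against 172 ± 83.5 TPM (log2 change -4.08 ± 0.67, adjusted p = 0.00391). The interferon-induced genes Ifit1 and Isg15 were at 12.4 ± 3.57 TPM against 1.16 ± 0.387 TPM (log2 change 2.62 ± 0.24, adjusted p = 2.02e-04) and 75.0 ± 31 TPM against 15.6 ± 6.85 TPM (log2 change 2.20 ± 0.38, adjusted p = 0.00429).

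In all, 806 genes rose and 2040 fell, 2846 in total. A limma fit of only the 2 groups compared called 727 genes and kept 25.2% of the 2846. Acute phase genes fell in 14 of 20 cases (16 adjusted over the list alone, median log2 change -2.16, camera adjusted p = 2.30e-07, and 0.976 with estimated correlation), including Orm2 and the fibrinogen genes Fga and Fgb (adjusted p = 0.00185 to 0.00325). Interferon response genes rose in 9 of 20 cases (10 adjusted over the list alone, median log2 change 0.85, 0.51 to 1.33 without 1 library, camera adjusted p = 1.26e-08, and 0.976 with estimated correlation). Mitochondrially encoded genes rose in 7 of 13 (9 adjusted over the list alone, median log2 change 0.96, 0.60 to 1.17 without 1 library, camera adjusted p = 3.28e-07, and 0.976 with estimated correlation), beside the mitochondrial shares of 15.3% ± 6.30 and 8.10% ± 0.627 given above. Of the 25 lists tested only these 3 passed, so the members of other lists that follow are single genes and not shifts of their lists. Among genes of the stress response, Creld2 (152 ± 71.6 against 17.2 ± 1.87 TPM) and Manf (417 ± 172 against 105 ± 30.5 TPM), both induced by unfolded protein, rose, while Asns and Atf5, targets of amino acid shortage, fell (adjusted p = 0.00410 to 0.0140). Of hepatocyte genes, the urea cycle gene Cps1 (88.6 ± 33.3 against 331 ± 125 TPM) fell and the apolipoprotein gene Apoc3 (10166 ± 1379 against 5127 ± 637 TPM) rose. Among fat metabolism genes, Pdk4 was at 0.703 ± 0.497 TPM against 11.4 ± 3.22 TPM (log2 change -2.87 ± 0.30, adjusted p = 5.07e-04), Fitm1 rose and Plin3, Slc27a5, Slc27a4 and Me1 fell (adjusted p = 0.00312 to 0.0123), as did Cyp8b1, Tat, Fbp1 and Hadha (adjusted p = 0.00620 to 0.0121). The lists of fatty acid oxidation (camera adjusted p = 0.884) and of fatty acid uptake and lipid droplets (0.794) did not pass. The median of the oxidation list, -0.11, turned positive with every scaling tried. H2-Q1, Rny3, Hsd3b1 and Elavl4, a neuronal RNA-binding protein gene, rose (adjusted p = 2.06e-07 to 0.00386), and Aldh4a1 and Mmd fell (adjusted p = 9.67e-04 to 0.00235).

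The count of 2846 dropped to 1808 without KO LFD library 2, 1607 without KO LFD library 5, 1635 without KO HFD library 1 and 1888 without KO HFD library 5. The genes named above for this comparison passed in every fit without 1 library that tested them, as did the 3 lists. Cyp2d34 rose and Rps13-ps1 fell with HFD as well, but lost the call in 8 and 4 of those fits (adjusted p up to 0.139 and 0.0828). The levels of n-R5s139, n-R5s141 and Rpl17-ps3, which rose, and of Tmem254c and Rps13-ps1 are uncertain for their copies (adjusted p = 5.58e-04 to 0.0239). Of the calls, 71.7% were lower as deposited, 51.1% with median-ratio scaling, 56.2% with quantile normalization, 53.7% without mitochondrial genes and 52.7% with the GC and length correction. These scalings raised the median over all genes by 0.22, 0.17, 0.17 and 0.21. Without KO LFD libraries 2 and 4, which held little Dbp, 1163 genes passed.

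The diet effect differed between the genotypes for serum amyloid genes, for Cd36 and for many of the genes set apart in the KO HFD livers, in the test of the interaction itself. The KO HFD libraries, which enter every interaction, also stood apart in mitochondrial share, Malat1 and Neat1, as given above. Saa1 was higher with the knockout label on LFD and did not pass on HFD (adjusted p = 0.0734), an interaction of log2 change -9.71 ± 1.13, adjusted p = 0.00369, and Saa2 had log2 change -11.13 ± 1.34, adjusted p = 0.00401. For Cd36 the difference between labels was larger on HFD, with an interaction of -1.98 ± 0.51 (adjusted p = 0.0379). Interactions of H2-Q1, Rny3, Mmd and Tmem254c, the last with copies elsewhere, were 5.80, 5.58, -4.70 and -5.06 (adjusted p = 1.06e-05 to 0.0126).

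In all, 304 interactions were positive and 853 negative. Of 100 splits of the libraries, 5 reached this count of 1157, the real one included, so chance was not excluded for it. Without a filter 182 passed. Acute phase genes were negative in 14 of 20 cases past the threshold (19 adjusted over the list alone, camera adjusted p = 2.38e-08, and 0.936 with estimated correlation). Mitochondrially encoded genes were positive in 3 of 13 (7 adjusted over the list alone, camera adjusted p = 3.10e-08, and 0.936 with estimated correlation). Bile acid genes (5 negative, 12 adjusted over the list alone, camera adjusted p = 0.0254, and 0.936 with estimated correlation) and cholesterol synthesis genes (2 negative, 3 adjusted over the list alone, camera adjusted p = 0.0151, and 0.936 with estimated correlation) shifted downward. Endothelial markers shifted upward (2 positive, median -0.04 to 0.40 without 1 library, 2 adjusted over the list alone, camera adjusted p = 0.0419, and 0.936 with estimated correlation). The bile acid call was lost without KO LFD library 4 (0.0688). The cholesterol call was lost without KO LFD library 2 (0.0561) or 5 (0.0505) or KO HFD library 5 (0.0991). The endothelial call was lost without WT LFD library 4 (0.0552) or 8 (0.0877), WT HFD library 2 (0.116), KO LFD library 4 (0.0688) or 5 (0.0507) or KO HFD library 6 (0.0628). The count of 1157 became 221 and 46 without WT LFD library 7 and 8, 24 and 60 without WT HFD library 1 and 6, 350, 2047 and 331 without KO LFD library 2, 4 and 5, and 533 without KO HFD library 5. Cd36 lost the call without WT LFD library 7 or 8, any of the 3 WT HFD libraries, KO LFD library 5 or KO HFD library 1 (adjusted p up to 0.0998). Saa1, Saa2, H2-Q1, Rny3, Mmd and Tmem254c passed in every fit without 1 library that tested them. They were the only 6 to do so of the 45 named genes that passed here, and the other 39 lost the call in at least 1 fit. Lcn2, which encodes the iron-binding acute phase protein lipocalin 2, had an interaction of -6.69 ± 1.92 (adjusted p = 0.0493) and lost the call in 9 of 12 fits (adjusted p up to 0.119). Of the interactions called, 73.7% were negative as deposited, 53.3% with median-ratio scaling, 53.9% with quantile normalization, 55.7% without mitochondrial genes and 53.1% with the GC and length correction. The median over all genes shifted by 0.29, 0.25, 0.20 and 0.29.

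Averaged over both diets, livers labelled knockout held higher levels of endothelial, matrix and macrophage genes and lower levels of fatty acid oxidation genes than WT livers. Each of these list calls was lost with estimated correlation (lowest adjusted p = 0.254). The KO HFD libraries in this average also stood apart in mitochondrial share, Malat1 and Neat1, as given above. The fatty acid binding protein gene Fabp4 was at 10.9 ± 4.07 and 9.84 ± 1.77 TPM in KO LFD and KO HFD livers against 2.21 ± 1.24 and 2.37 ± 0.808 TPM in WT livers (log2 change 1.82 ± 0.24, adjusted p = 0.00161). The fatty acid transporter gene Slc27a2 was at 544 ± 171 and 443 ± 80.6 TPM against 1119.7 ± 149 and 1199 ± 17.1 TPM (log2 change -1.26 ± 0.17, adjusted p = 0.00159). Cd36 had an average log2 change of -1.48 ± 0.25 (adjusted p = 0.00440). Albumin, Alb, was at 19976 ± 2335 and 21183 ± 3532 TPM against 39941 ± 10652 and 41241 ± 5509.7 TPM (log2 change -0.97 ± 0.17, adjusted p = 0.00537).

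In all, 1094 genes were higher and 1486 lower in this average of 6 against 6 libraries. Endothelial markers rose in 11 of 11 cases (11 adjusted over the list alone, camera adjusted p = 3.69e-10, and 0.254 with estimated correlation), with log2 changes of Fcgr2b (1.32 ± 0.18, adjusted p = 0.00160) and Cdh5 (1.01 ± 0.17, adjusted p = 0.00417). Matrix genes rose in 12 of 22 (15 adjusted over the list alone, camera adjusted p = 4.79e-09, and 0.751 with estimated correlation), with the cytokine gene Tgfb1 (0.86 ± 0.14, adjusted p = 0.00347) and the matrix glycoprotein gene Sparc (0.998 ± 0.20, adjusted p = 0.00765). Kupffer cell markers rose in 12 of 14 and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 8.96e-07, and 0.751 with estimated correlation), with Cd68 (1.73 ± 0.30, adjusted p = 0.00456) and the complement gene C1qa (1.67 ± 0.40, adjusted p = 0.0156). Cytokines and chemokines rose in 4 of 14 (4 adjusted over the list alone, camera adjusted p = 0.0190, and 0.765 with estimated correlation), with Cxcl16 (0.77 ± 0.18, adjusted p = 0.0140). Acute phase genes rose in 7 of 20 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0147, and 0.820 with estimated correlation), Il1rn being the gene that fell, while on HFD alone 6 of 20 fell and none rose. Fatty acid oxidation genes fell in 16 of 27 (20 adjusted over the list alone, camera adjusted p = 5.37e-06, and 0.751 with estimated correlation), with Cpt1a (-1.38 ± 0.27, adjusted p = 0.00709). Lipid droplet genes fell in 9 and rose in 2 cases of 24 (13 and 2 adjusted over the list alone, camera adjusted p = 0.0125, and 0.751 with estimated correlation). Hepatocyte genes fell in 5 of 20 (5, camera adjusted p = 0.0125, and 0.751 with estimated correlation). Bile acid genes fell in 7 of 19 (10, camera adjusted p = 0.0158, and 0.751 with estimated correlation).

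Averaged over diets, the mitochondrially encoded list shifted upward (camera adjusted p = 0.0355, and 0.820 with estimated correlation) although its only changed member, mt-Atp8, fell (0 adjusted over the list alone). Unfolded protein genes shifted upward (2 of 17 rose, 1 adjusted over the list alone, camera adjusted p = 0.0483, and 0.820 with estimated correlation). The bile acid call was lost without KO LFD library 5 (0.0502). The acute phase call was lost without KO LFD library 5 (0.0852). The unfolded protein call was lost without WT LFD library 7 (0.104) or 8 (0.0518), WT HFD library 1 (0.0999) or 2 (0.0921), KO LFD library 5 (0.0852) or KO HFD library 6 (0.171). The mitochondrial call was lost without WT LFD library 4 (0.0938), WT HFD library 1 (0.0766) or 6 (0.0619), KO LFD library 4 (0.0536) or KO HFD library 1 (0.477). The largest rises in the average included H2-Q1 (3.87 ± 0.40, adjusted p = 6.07e-04), Saa2 (3.31 ± 0.67, adjusted p = 0.00817) and Rny3 (2.79 ± 0.16, adjusted p = 1.06e-05). Saa2 went opposite ways on the diets (log2 change 8.87 on LFD and -2.25 on HFD, adjusted p = 0.00376 and 0.0805). The largest falls included Mmd (-2.59 ± 0.34, adjusted p = 0.00159), Snora20 (-2.54 ± 0.59, adjusted p = 0.0132) and the acyl-CoA thioesterase gene Acot3 (-2.19 ± 0.68, adjusted p = 0.0404), which lost the call in 9 of 12 fits (adjusted p up to 0.0810). The heat shock gene Hspa1b (-2.35 ± 0.61, adjusted p = 0.0203) and the glucuronosyltransferase gene Ugt1a9 (-2.30 ± 0.39, adjusted p = 0.00428) fell as well, with levels uncertain for copies. The mt-Atp8 call was lost in every fit except that without KO HFD library 1 (adjusted p up to 0.104). The count of 2580 dropped to 1552 without WT LFD library 4, 1428 without WT HFD library 1 and 1486 without WT HFD library 6.

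**Figure D4:**
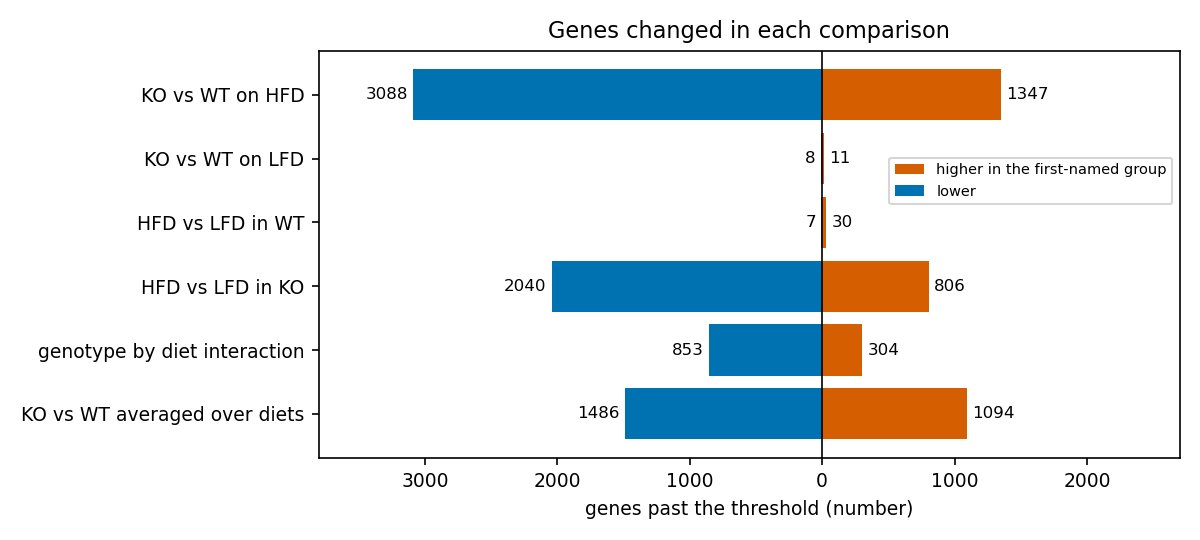
Genes past adjusted p of 0.05 by limma (x axis, number of genes) in each of the 6 comparisons (y axis), with genes higher in the first-named group to the right and lower ones to the left, and for the interaction positive and negative values. The bar for livers labelled knockout against WT on HFD is the longest, with 1347 higher and 3088 lower genes.

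The diet effects of the 2 genotypes showed little relation across all genes, although the genes called in both moved alike. Over the 11980 genes, log2 changes with diet in WT and in livers labelled knockout correlated with Pearson's r = -0.01 and Spearman's rho = -0.06. Genes are not independent replicates, so no p is given. The 2 comparisons called 14 genes in common as higher (independent lists would give 2.02), 4 as lower (1.19 expected) and 0 in opposite directions. Ifit1 rose and Pdk4 fell with HFD in both genotypes. Differences between labels on HFD and on LFD correlated with r = 0.15 and rho = 0.20, against a mean r of -0.00347 for simulated unchanged groups. The simulation drew each gene independently and gave only a mean, so it cannot show whether 0.15 exceeds chance for genes that vary together. Without WT LFD library 4 the r of the data dropped to 0.03. In these comparisons 3 genes were higher (1.24 expected) and 3 lower (2.06 expected) on both diets, with 1 opposite. Fam25c was among those higher on both diets (log2 change 2.49 on LFD and 1.11 on HFD, adjusted p = 0.00806 on HFD).

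The diet effect in WT livers and the difference between labels on HFD share the WT HFD libraries, which enter with opposite sign. Of the 30 genes raised by HFD in WT livers, 16 were lower with the knockout label on HFD (independent lists would give, ignoring the shared libraries, 7.73) and 26 had a negative change. Cfd, at 0.430 ± 0.501, 158 ± 98.8 and 8.63 ± 9.13 TPM in WT LFD, WT HFD and KO HFD livers, was an example. Across all genes the 2 effects correlated with r = -0.38 and rho = -0.41. Simulated unchanged groups that share these libraries, with genes again drawn independently, gave a mean r of -0.50, further from 0. The covariance was -0.152 against -0.0578 in the simulation, a difference of -0.0947, and with 3 shared libraries the controls could not be split, so part of the relation can come from those libraries.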

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

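The tests of shared gene copies, of time of day and of swapped libraries were chosen after the result was seen. So were the fits without mitochondrial genes and with the GC and length correction, which the first pattern uses. The difference between livers labelled knockout and WT differed between the diets, by the interaction test, for 25 of the genes named for either diet (adjusted p = 1.06e-05 to 0.0436). Acute phase genes rose with the label on LFD and had negative interactions: Saa2 (-11.13), Saa1 (-9.71), Orm2 (-7.03), Saa3 (-5.32) and Hpx (-2.46) on the log2 scale. Fam25c, Ighv1-72 and Slc13a3 rose on LFD too, with interactions of -1.37, -1.96 and -2.55, while Lepr and Gys2 fell on LFD, with interactions of 2.25 and 1.49. Genes that rose with the label on HFD had interactions of 8.90 for Cyp2d34, 5.80 for H2-Q1, 5.58 for Rny3, 6.74 for Hsd3b1, and, with copies elsewhere, 8.55 for n-R5s139, 9.16 for Mir703, 5.03 for Rpl17-ps3 and 5.71 for Cyp2c69. Genes that fell on HFD had interactions of -1.98 for Cd36, -5.54 for Aldh4a1, -4.70 for Mmd, -4.02 for Cfd and, with copies elsewhere, -5.06 for Tmem254c, -3.50 for Ugt1a1 and -3.07 for Pdf. Of 17 of these genes with fits without 1 library, 6 passed in every such fit and 11 lost the call in at least 1. For the other 8, interactions in such fits are not reported here. The number that lost it was 5 without WT LFD library 7 (0.0594 to 0.0926), 9 without WT LFD library 8 (0.0526 to 0.110), 11 without WT HFD library 1 (0.0501 to 0.112), 2 without WT HFD library 2 (0.0563 to 0.0610), 7 without WT HFD library 6 (0.0502 to 0.101), 4 without KO LFD library 2 (0.0527 to 0.0767), 5 without KO LFD library 5 (0.0551 to 0.0747), 4 without KO HFD library 1 (0.0523 to 0.0848), 2 without KO HFD library 5 (0.0698 to 0.0707) and 1 without KO HFD library 6 (0.0536), with the adjusted p in parentheses.

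A first pattern is the distance of KO HFD livers from WT HFD livers, with 4435 genes called. A larger mitochondrial share and GC content or transcript length were weighed as technical explanations. Without mitochondrial genes and their copies, 91.7% of the called genes still passed in the same direction, and with the GC and length correction 79.7%, which argues against either as the whole cause, although both changed the balance of rises and falls. Differences in RNA quality, handling or library batch between the groups, which the sources used here do not describe, and effects of the genotype stay open, as no value here separates them. The 6 HFD libraries make 10 splits, too few for a share under 0.05, with 1 split, the real one, reaching 4435 genes and 3 genes as the highest of the other splits.

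Within this pattern, 12 genes were on or off in KO HFD livers alone, with a ratio of at least 8 to every other library and a mean of at least 5 TPM. They were chosen after their values were seen: 5 were on, as Bicd1 (9.16 against 0.118 TPM) and Fam221b (13.9 against 0.149 TPM) with H2-Q1, Rny3 and Snora64, and 7 off, as Klhl32 (0 against 6.20 TPM) and Prps1l3 (0.0733 against 5.82 TPM) with Mmd, Tmem254c, Gm5831, Gm8325 and Gm9797. Reads shared between copies may account for some of these, since 4 of 12 (33.3%, exact 95% confidence interval 9.92% to 65.1%) shared at least 0.5 of their 31-base words with another gene. That interval is too wide to decide on copies as a general cause, and Bicd1, Fam221b, H2-Q1, Rny3, Snora64, Klhl32, Mmd and Prps1l3 had no such copy. The small RNAs Rny3 (31.8 to 67.4 TPM) and Snora64 (6.81 to 13.1 TPM) were at 0 TPM in every library outside KO HFD. Gm5831, Gm8325, Gm9797 and Klhl32 were at 0 TPM in every KO HFD library. Whether handling or library batch set these genes apart, rather than the genotype, was not tested.

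A further pattern is the rise of acute phase genes in KO LFD livers. Hour of collection was weighed, because KO LFD libraries 2 and 4 held 0.930 and 4.95 TPM of the clock output gene Dbp against 64.3 TPM in library 5. The median rise over the 20 acute phase genes was 1.08 and 1.84 in libraries 2 and 4 and 2.71 in library 5, which is 131% of the median over all 3 (2.07). Time of day is thus an unlikely cause of the whole rise, but that rests on 1 library and cannot exclude it. An inflammatory response in these animals, from the genotype, an infection or an injury, was not tested and stays open. The 6 LFD libraries make 10 splits, too few for a share under 0.05, with 1 split, the real one, at 19 genes and 3 as the highest other.

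The last pattern weighed is Lix1l, at 1.15 TPM in KO HFD and 1.27 TPM in WT HFD livers, for which a swap of libraries between these groups was weighed with the 19 genes called between the LFD groups. By these, 4 of the 6 HFD libraries lay on the side of their own label: WT HFD libraries 1, 2 and 6 had 4, 5 and 5 genes on the knockout side, and KO HFD libraries 1, 5 and 6 had 7, 10 and 9. Of these genes, 14 of 19 had a called interaction and 9 went the other way on HFD, so these sides do not bear on a swap. Entpd4b (1.95 to 3.69 TPM in livers labelled knockout and 5.29 to 14.2 TPM in WT livers) and Wdfy1 (2.56 to 4.94 TPM in livers labelled knockout and 0.960 to 1.88 TPM in WT livers) separated the labels in all 12 libraries but were chosen after their values were seen, so a wrong label could not be excluded. Transcript from outside the deleted part of Lix1l may be present and could not be separated from full transcript in gene totals.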

How the results depend on the processing

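The fits without mitochondrial genes, with the GC and length correction, of protein-coding genes, without genes with copies and without the 2 KO LFD libraries with little Dbp were chosen after the result was seen, as was the check of the animal numbers. The cause of each change below was not tested, except that fits of fewer libraries, and the fit with a block, have fewer degrees of freedom. Cd36 was lower in KO HFD than in WT HFD livers past the threshold under every alternative. Apart from Lix1l and Cd36 in the 4 comparisons within a diet or genotype, whose changes are given below, among fits of genes that the naming rule allows, 7716 values kept their direction and side of the threshold, 1222 no longer passed, 25 newly passed and 3 reversed. Of list tests, counted only for lists that had passed, 1070 kept both, 160 no longer passed and 7 reversed the direction of the test.

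On LFD the count of genes called between labels, 19, was 8 with a pseudocount of 0.1, 12 without a filter, 52 with median-ratio scaling, 45 with quantile normalization, 0 in the limma fit of 2 groups (1524 with unadjusted p under 0.05 in the fit of all libraries), 35 without mitochondrial genes and 41 with the GC and length correction. For HFD in WT livers the count, 37, was 8 without a filter, 19 with at least 5 TPM, 214 in the fit of 2 groups and 64 with the GC and length correction. HFD in livers labelled knockout gave 727 genes in the fit of 2 groups, and the interaction 182 without a filter and 1764 with the GC and length correction. Lists passing numbered 11 on HFD between labels and 6 for HFD in livers labelled knockout without a filter, 2 for the interaction with at least 5 TPM, and 11 on HFD with the GC and length correction. With an estimated correlation, camera passed 0 lists in all 6 comparisons.

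Cd36 with HFD in WT livers passed with a pseudocount of 5 (1.55, adjusted p = 0.0440), in the fit of 2 groups (1.80, adjusted p = 0.0260), among protein-coding genes (1.79, adjusted p = 0.0464) and without genes with copies (1.80, adjusted p = 0.0472). Its change with HFD in livers labelled knockout turned to 0.0754, 0.0437 and 0.01004 with median-ratio scaling, quantile normalization and without mitochondrial genes. Lix1l on HFD turned to 0.18 with the GC and length correction.

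With array weights the counts were 7733 on HFD and 71 on LFD between labels, 2598 and 4194 for HFD in WT livers and in livers labelled knockout, 4893 for the interaction and 4768 averaged over diets, with 13 lists on HFD and 5 for HFD in livers labelled knockout. Lix1l then passed on HFD (-0.73, adjusted p = 0.0138) and turned to -0.16 with HFD in livers labelled knockout and -0.30 for the interaction, and Cd36 had 1.91, adjusted p = 0.00287 with HFD in WT livers and 0.18 in livers labelled knockout.

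With the animal number as a block, 2693 genes were called on HFD, 10 and 553 for HFD in WT livers and in livers labelled knockout, 18 for the interaction and 710 averaged over diets, and 6 and 10 lists passed for HFD in livers labelled knockout and the interaction. Lix1l with HFD in WT livers turned to -0.25. The direction of the list test reversed on LFD for cholesterol synthesis (median -0.65), female-biased (-0.20) and mitochondrially encoded genes (0.15). The median of the female-biased genes stayed negative, as in each fit without 1 library. With HFD in WT livers the test reversed for fatty acid oxidation (median 0.13), cholesterol synthesis (-1.93) and mitochondrially encoded genes (0.26), and in the interaction for cholesterol synthesis (0.10). Numbers 7 and 8 occurred only in WT LFD livers, so with the block each comparison that uses this group rested on WT LFD library 4. All the list tests that reversed were in such comparisons. The numbers did not pair libraries: deviations from group means correlated at -0.16, -0.26, -0.09, 0.10 and 0.09 in the 5 pairs with the same number, and from -0.37 to 0.31 in others.

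Without KO LFD libraries 2 and 4, where the single KO LFD library left is assumed to vary like the other groups, 84 genes were called on LFD, 197 and 1163 for HFD in WT livers and in livers labelled knockout and 1082 averaged over diets, and 6 lists for HFD in livers labelled knockout. Cd36 was at 0.41 on LFD and 1.80 with HFD in WT livers, and Lix1l had an interaction of -0.17.

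Leaving out 1 library at a time gave 2327 to 4652 genes on HFD and 4 to 64 on LFD between labels, 1 to 97 and 1607 to 2947 for HFD in WT livers and in livers labelled knockout, 24 to 2047 for the interaction and 1428 to 2687 averaged over diets. Lists passing ranged from 5 to 11, 10 to 13, 6 to 11, 3 to 5, 4 to 8 and 8 to 13 in the same order. Lix1l ran from -0.44 to 0.23 on HFD and 0.24 to 0.91 with HFD in livers labelled knockout (adjusted p = 0.0336 without KO HFD library 5) while its interaction was -0.0910 without KO HFD library 1 and 0.58 without KO HFD library 5. Cd36 ran from -2.73 to -2.34 on HFD, and 1.64 to 1.95 and -0.48 to 0.27 with HFD in WT livers and in livers labelled knockout. Without read depth, differences of genes near the floor of 1 TPM cannot be set against counting error.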

Other observations

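The test of gene position was planned, while the genes named in this part were chosen after their values were seen. Only 3 genes passed as higher and 3 as lower on both diets, so the genes below rest on the test of the average over diets. The actin regulator gene Coro2b was at 30.8 and 113 TPM in KO LFD and KO HFD livers against 6.65 and 17.5 TPM (average log2 change 2.30, adjusted p = 0.00154). The complement gene C4a was at 15.6 and 84.3 TPM in KO LFD and KO HFD livers against 3.33 and 12.4 TPM (average log2 change 2.21, adjusted p = 0.00178). The centrosomal gene Cep85 was at 178 and 827 TPM in KO LFD and KO HFD livers against 58.9 and 99.0 TPM (average log2 change 2.21, adjusted p = 0.00255). Among lower genes, Abhd2 was at 6.67 and 3.18 TPM in KO LFD and KO HFD livers against 23.9 and 17.3 TPM (average log2 change -1.93, adjusted p = 0.00276). Wdfy1, which acts on endosomes, was at 2.56 to 4.94 TPM in livers labelled knockout and 0.960 to 1.88 TPM in WT livers. Entpd4b, a nucleotidase gene, was at 1.95 to 3.69 TPM in livers labelled knockout and 5.29 to 14.2 TPM in WT livers, so its ranges do not overlap, and Nnt, the nicotinamide nucleotide transhydrogenase of mitochondria, was at 30.1 to 65.4 TPM in livers labelled knockout and 21.5 to 32.1 TPM in WT livers.

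Knockout mice and their controls can differ in the strain of origin of DNA around the altered gene, and the strain of these mice is not given in the sources used here. Genes called in the average over diets, and with no overlap between the labels on either diet, numbered 765, 415 higher and 350 lower. Of genes within 10 Mb of Lix1l, 14 of 203 were among them, and of all others 751 of 11777, an odds ratio of 1.09 (95% confidence interval 0.580 to 1.88, Fisher's exact 2-sided p = 0.771). Genes near Lix1l were thus not over-represented by this test. The window held only 203 of the genes tested, so the test could not have shown local DNA to explain the set of 765. Segments elsewhere in the genome were not tested.

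Other splits of the libraries were tested for the remaining comparisons. For HFD in WT livers, the real split called 37 genes and the highest of the others 1, and for HFD in livers labelled knockout 2846 and 15. In each case 1 of 10 splits was as large, the real one, and 10 splits are too few for a share under 0.05. For the average over diets, 1 of 100 splits, the real one, reached 2580 genes, with 1333 as the highest other drawn. An interaction split is the split of the average with its LFD sides exchanged, and with both draws 2 of 144 distinct splits reached 2580, the other calling 3809 genes. The share over all 12 libraries was thus under 0.05, but it rested on the KO HFD libraries staying together. Of only 13 splits that kept all 3 of them together (71 to 3809 genes), 2 reached 2580, and the 131 others called at most 6. Chance among the LFD libraries was therefore not excluded, and the HFD libraries alone make too few splits to exclude it. For the interaction, 5 of 100 splits reached 1157 genes and the highest other called 3809, so chance was not excluded. That highest count, several times the real one, came from a split that kept all 3 KO HFD libraries together. The 4 splits with more genes than the real one were among the 10 other splits of that kind (126 to 3809 genes), which kept the difference between labels on HFD. The 89 splits that parted these libraries called at most 4. Large counts thus came only with the KO HFD libraries kept together. Such splits are not free of change, and they do not show that the count depends on the LFD labels.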
